A study of Mus musculus with 17 samples.

How the data were processed

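Bulk RNA-seq libraries from dissected mouse kidneys at E12.5 were analysed. The 17 libraries comprised 5 with stabilised beta-catenin in the stroma (Foxd1-Cre), 3 with it in nephron progenitors (Six2-Cre) and 9 wild types, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, kidneys were kept in RNAlater, RNA was extracted with the RNeasy Micro kit and libraries were prepared by standard Illumina protocols, with no statement on strand or on selection of polyadenylated RNA.

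Per the submitters' processing notes, base calls were made with bcl2fastq 2.17.1.14 and transcripts were quantified with Salmon on GRCm38. The authors deposited 1 table of FPKM values with 24432 gene IDs and 17 libraries, and read counts were not used here. The gene-level summary, the annotation release and any scaling between libraries are not stated. Total FPKM per library ran from 799273 to 963729 while the upper quartile of the genes ran only from 15.1 to 15.9, so a scaling other than the plain total cannot be excluded. Gene IDs were matched to symbols and places in GENCODE release 21 for mouse (GRCm38), where 24189 had a symbol and 243 had none. In all libraries 3300 IDs were at 0, and 3 symbols stood on 2 rows each, which were kept apart.

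Depth was not given. For each library the smallest step between FPKM values, multiplied by transcript length in kilobases, was read off genes with transcripts of 1500 to 4000 bases, and gave 28800000 to 37600000 reads for 11 libraries and 5300000 to 5840000 for 6. The widest gap in the number of genes at 0 per library separated the same 11 libraries (5312 to 5807 genes) from the same 6 (7590 to 7891 genes), and these were called library set 1 and library set 2. In set 1 a value of 1 read corresponded to 0.0266 to 0.0347 FPKM for a transcript of 1 kilobase, and in set 2 to 0.171 to 0.189 FPKM, so small values were less precise in set 2. These read steps cover counting error only.

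The comparisons, gene lists and tests below were fixed before the data were examined, except where stated. Genes with at least 1 FPKM in at least 3 libraries were kept (14014), values were transformed as log2(FPKM + 1), and a linear model with 3 group means was fitted with limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjustment over all genes. A call was an adjusted p under 0.05, two-sided. Errors beside log2 changes are limma's standard errors (SE), and those beside FPKM are standard deviations (SD). This planned comparison pools both library sets.

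After the library sets had been seen, each mutant was fitted with the wild types of its own set alone (5 against 6 libraries in set 1, 3 against 3 in set 2), and these values lead the results. Genes at 0 in every library of a set were left out there, which left 13996 and 13828 genes. The difference of the mutant effects was the Foxd1-Cre effect minus the Six2-Cre effect, with the squared errors added and Satterthwaite degrees of freedom, for 13810 genes. There were 3 versions of this within-set analysis. A joint fit of 4 group-by-set means with equal variance came first and called 3638 genes for Six2-Cre, and a joint fit with 1 weight per set came next. The separate fits were adopted because set 2 varied more than set 1 and because, in 10 simulations with 200 changed genes, 19.2% of the calls for the difference were false on average with the weighted joint fit and 11.5% with the separate fits. Camera's list tests of the difference still use the fit with 1 weight per set, since they need 1 fit, and share its limits.

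For gene groups, 31 lists of cell type markers and pathways were written down in advance, and the 28 with at least 5 measured members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera asks whether a list's genes move further than other genes. Counts per list are given over all genes tested and adjusted over the list alone. Named genes followed a rule: Ctnnb1, Foxd1 and Six2; the 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 2 FPKM in the higher group and no overlap between the groups, predicted genes and pseudogenes left out; and up to 4 members of each list with the smallest p-values. Genes named beyond the rule are marked where they appear. Among named genes, those for which the annotation has an overlapping or antisense gene (Abcc9, Alas2, Aldoa, Bmp4, Ccnd1, Cd34, Ctnnb1, Des, Ebf2, Ecm1, Fgf20, Fgfr1, Fgfr2, Fhl2, Gata3, H19, Hand2, Igf2, Mab21l1, Mecom, Meis1, Mest, Mrc1, Ntn1, Pax8, Penk, Rarb, Rmrp, Rnf43, Rpph1, Runx2, Sox5, Sox8, Tmem132c and the microRNAs, Scarna6, Snora33 and Snord92) have uncertain values, since counting by strand is not stated.

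The agreement between the mutant effects was measured as a Pearson correlation and covariance across genes and as shared calls, set beside 100 simulations of unchanged groups against the same 9 wild types and beside 2 splits of the wild types. Replicate numbers were tested for pairing by correlating the deviations of same-numbered libraries from their group means. Of 11 such pairs 0 had a correlation over 0.1 (highest 0.0993), and the labels do not say what a number marks, so no pairing was used. The pairs within library set 1 were all positive, so a weak pairing there was not excluded. A library far from the rest of its group was sought with Dixon's test at 95% in groups of 4 to 10 libraries. Splits of the libraries into groups of the same sizes were drawn up to 100 times per comparison.

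Alternatives tried were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, median-of-ratios scaling, rescaling to the same sum, quantile normalization, fits without the variance trend, with library weights, with Y-linked or erythroid expression as a covariate, with the replicate number as a block, on the compared groups only, a fold change of at least 2, and each library left out in turn. Those added after the data were seen were each library set by itself, protein-coding genes only and the joint fits. List tests were repeated with the estimated correlation, fry, median-of-ratios scaling, a pseudocount of 0.1, the block and each library left out.

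The fits were tested on simulated data with the real libraries' means and spreads and 200 changed genes among 14014, with a difference between the sets. For Foxd1-Cre within set 1, 86.6% of changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2 on the log2 scale were recovered, and 3.55% of calls were false. For Six2-Cre within set 2 these were 41.8%, 67.2% and 92.4%, with 2.19% false. For the difference of effects they were 50.7%, 82.1% and 89.4%, with 11.4% false, above the 5% aimed at. For the pooled fits 8.62%, 72.1% and 97.9% of the calls were false for Foxd1-Cre, Six2-Cre and the direct comparison. Camera called the list that had been moved. Of 200 lists that had not been moved, 4 passed an unadjusted threshold of 0.05. The simulated genes varied independently of each other, so this does not test the preset correlation for real lists, whose genes may vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9 from tables made with pandas 2.3.3 and NumPy 2.4.6.

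Reads were not available, so exon 3 of Ctnnb1, strand, mapping and read quality were not examined. Lists with fewer than 5 measured members (proximal tubule, gonad and germ cells, Y-linked) received counts but no list test.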

Results

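RNA was sequenced from whole kidneys dissected from mouse embryos at E12.5, when nephron progenitors, stroma and ureteric bud are all present. In 5 libraries a stabilised form of beta-catenin, the transcriptional effector of Wnt signalling made by Ctnnb1, was switched on in the stromal lineage by Foxd1-Cre. In 3 libraries it was switched on in the nephron progenitor lineage by Six2-Cre. The remaining 9 libraries came from wild-type kidneys. Expression was given as FPKM for 24432 gene IDs, of which 24189 had a symbol. The 17 libraries fell into 2 library sets that the labels do not name, separated by how many genes were listed at 0. Library set 1 held the 5 Foxd1-Cre libraries and wild-type replicates 1 to 6, with 5312 to 5807 genes at 0 and total FPKM from 857705 to 963729. Library set 2 held the 3 Six2-Cre libraries and wild-type replicates 7 to 9, with 7590 to 7891 genes at 0 and total FPKM from 799273 to 834838. Read counts were not used here. The smallest step between values corresponded to 28800000 to 37600000 reads per library in set 1 and 5300000 to 5840000 in set 2.

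The wild types themselves differed between the library sets at 9172 of 14014 genes by limma. The first principal component held 66.0% of the variance and separated the sets, and the next held 6.30% and separated both mutants from the wild types. Each mutant was therefore set against the wild types of its own library set, a choice made after the data were seen. The gene and list totals of the planned comparison, which pools all 9 wild types, close the account of each comparison, with the lists whose calls differ there. No library of one mutant shared a library set with the other, so the mutants were compared only through their own controls.

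**Figure D1:**
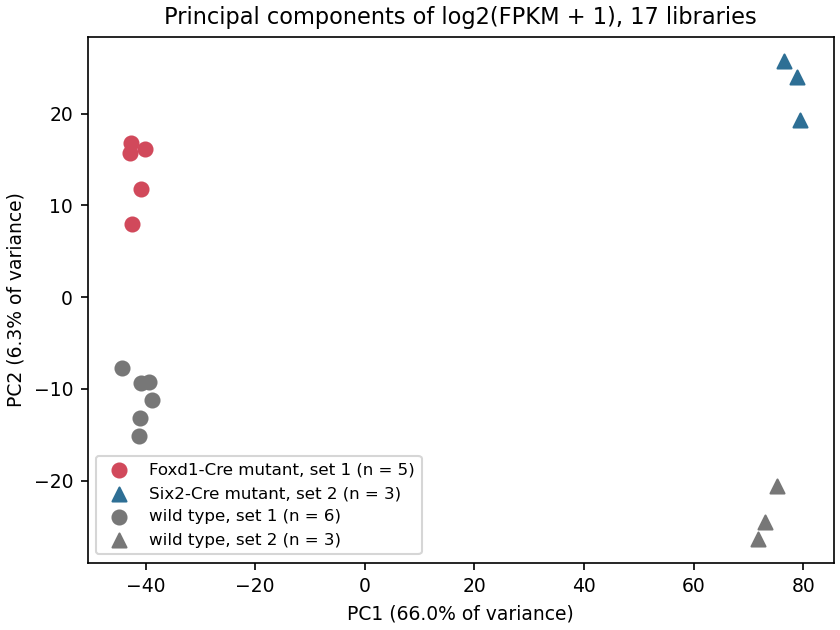
Positions of the 17 libraries on principal components 1 (x axis, 66.0% of the variance) and 2 (y axis, 6.30%) of log2(FPKM + 1), coloured by genotype. The 6 libraries of set 2 lie at 71.7 to 79.4 on component 1 and the 11 of set 1 at -44.4 to -38.8, and the mutants of each set lie above its wild types on component 2.

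Ctnnb1 (ENSMUSG00000006932, GRCm38 chromosome 9, 120929216 to 120960507) was at 509 ± 13.2 FPKM (SD, n = 5) in Foxd1-Cre kidneys and at 463 ± 35.0 FPKM (SD, n = 6) in their wild types. Its log2 change of 0.14 ± 0.05 (SE) did not pass the test (adjusted p = 0.105). In Six2-Cre kidneys Ctnnb1 was at 406 ± 7.05 FPKM (SD, n = 3) against 343 ± 16.5 FPKM (SD, n = 3) and rose by 0.24 ± 0.05 on the log2 scale (adjusted p = 0.0214). That call ended without Six2-Cre replicate 1 (0.060), 2 (0.076) or 3 (0.077) or wild-type replicate 9 (0.056), and against all 9 wild types the change of Ctnnb1 was -0.04. The activating allele lacks exon 3, which a value for the whole gene cannot show, so Ctnnb1 did not check the genotype labels. Ctnnb1 overlaps Ulk4 and the antisense gene 4930593C16Rik, and the counting is not stated to use strand.

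Notum and Axin2, direct targets of the pathway, separated every mutant library from every wild type. Notum (ENSMUSG00000042988, chromosome 11, 120653788 to 120661175), a secreted enzyme that inactivates Wnt proteins, was at 161 ± 27.5 FPKM (SD, n = 5) in Foxd1-Cre kidneys and 59.0 ± 6.13 FPKM (SD, n = 3) in Six2-Cre kidneys. In the wild types it was at 2.70 ± 0.505 FPKM (SD, n = 6) in set 1 and 2.33 ± 0.694 FPKM (SD, n = 3) in set 2. Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a negative feedback target, was at 68.0 ± 6.80 FPKM (SD, n = 5) and 36.5 ± 4.08 FPKM (SD, n = 3) in the mutants against 10.1 ± 0.571 FPKM (SD, n = 6) and 13.0 ± 0.538 FPKM (SD, n = 3).

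**Figure D2:**
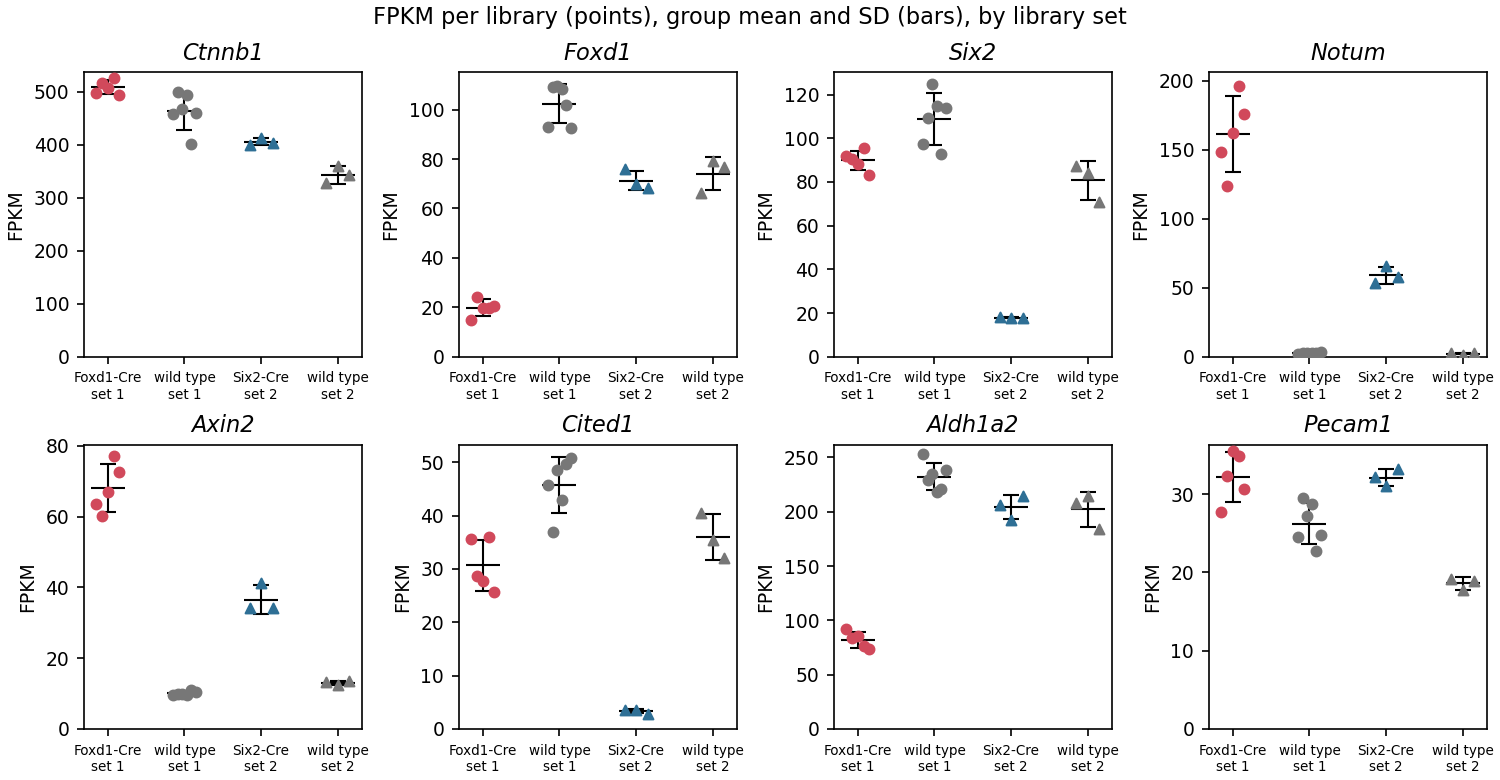
FPKM per library of 8 genes in Foxd1-Cre (n = 5), Six2-Cre (n = 3) and wild-type kidneys of library set 1 (n = 6) and set 2 (n = 3). Points are libraries, bars are group means and whiskers 1 SD, on linear axes. Foxd1 averages 19.9 FPKM in Foxd1-Cre kidneys against 102 in set 1 wild types, and Six2 averages 18.0 FPKM in Six2-Cre kidneys against 80.8 in set 2 wild types.

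The Foxd1-Cre comparison asked how active beta-catenin in the stroma alters the kidney, including the neighbouring nephron progenitors. Wnt target genes rose, and theirs was the 1 list of the 14 called by camera that held with an estimated correlation. Foxd1 itself fell with 9 other cortical stroma genes, and 12 of 18 hypoxia and glycolysis genes rose. Foxd1 (ENSMUSG00000078302, chromosome 13, 98354242 to 98359305), the transcription factor that marks cortical stroma, was at 19.9 ± 3.32 FPKM (SD, n = 5) against 102 ± 7.97 FPKM (SD, n = 6), a change of -2.32 ± 0.10 (SE) on the log2 scale (adjusted p = 1.9e-08). Aldh1a2, which makes retinoic acid, was at 82.1 ± 7.36 FPKM (SD, n = 5) against 232 ± 12.6 FPKM (SD, n = 6). The largest rises in log2 terms were those of Notum (5.45 ± 0.12, SE), Apcdd1 (4.89 ± 0.10), a Wnt inhibitor at the cell surface, Tmem132c (4.39 ± 0.08), Mybpc1 (4.06 ± 0.10), a muscle myosin-binding protein, and Mab21l1 (3.65 ± 0.10). Apcdd1 (ENSMUSG00000071847) lies at chromosome 18, 62922231 to 62961179. Mir1907 was at 13.8 ± 5.37 FPKM (SD, n = 5) and was listed at 0 in all 6 wild types of set 1. It lies within Trps1, Tmem132c overlaps its antisense gene Tmem132cos and Mab21l1 lies within Nbea, so their reads may be shared. Mir1907 is also far shorter than 1 kilobase, so its value may rest on few reads. The largest falls after Foxd1 were those of the chemokine Cxcl13 (-1.91 ± 0.28), the guidance factor Ntn1 (-1.62 ± 0.10), Aldh1a2 (-1.49 ± 0.06), Fibin (-1.48 ± 0.06) and the membrane peptidase Mme (-1.46 ± 0.09).

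Of 22 Wnt/beta-catenin target genes measured in Foxd1-Cre kidneys, 18 rose, 1 fell and 3 did not pass the test (18 rose and 2 fell when adjusted over the list alone). Among the rises were Apcdd1, Nkd1 (3.37 ± 0.09) and Axin2 (2.63 ± 0.06). The fall was in Dkk1 (-0.45 ± 0.10), a secreted Wnt inhibitor named after its value was seen. The list's median log2 change was 1.15, with adjusted p = 1.01e-25 by camera and adjusted p = 0.0274 with an estimated correlation.

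In the stroma of Foxd1-Cre kidneys, 10 of 21 cortical stroma genes fell, 4 rose and 7 did not pass (10 fell and 7 rose adjusted over the list alone). Foxd1, Ntn1, Aldh1a2 and Fibin led the falls, and the rises were in the retinoic acid receptor Rarb (0.30 ± 0.04), Gdf10 (0.87 ± 0.14), Slitrk6 (0.52 ± 0.09) and Lum (0.92 ± 0.22), named after their values were seen. The call of Lum ended without Foxd1-Cre replicate 3 (adjusted p = 0.0516). The median was -0.20 with adjusted p = 0.0255 by camera, and adjusted p = 0.456 with an estimated correlation. Camera's call ended without wild-type replicate 2 (median -0.25, adjusted p = 0.0587), and without Foxd1-Cre replicate 1 the median was -0.082. Of 18 medullary stroma genes 8 rose, 2 fell and 8 did not pass (8 and 4 adjusted over the list alone). Lef1 (2.38 ± 0.08), a partner of beta-catenin on DNA, Alx1 (2.60 ± 0.09), Myocd (1.13 ± 0.08), a smooth muscle coactivator, and Wnt5a (1.08 ± 0.10) rose, and Cdkn1c (-0.46 ± 0.05) and Fhl2 (-0.45 ± 0.08), named after their values were seen, fell. Lef1 is also a member of the Wnt target list. The median of the medullary stroma list was 0.22, with adjusted p = 8.1e-04 by camera and adjusted p = 0.353 with an estimated correlation.

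Of 22 nephron progenitor genes measured in Foxd1-Cre kidneys 6 fell, 1 rose and 15 did not pass (8 and 1 adjusted over the list alone). Six2, the progenitor transcription factor, was at 89.9 ± 4.55 FPKM (SD, n = 5) against 109 ± 11.8 FPKM (SD, n = 6), a log2 change of -0.27 ± 0.07 (adjusted p = 0.0283). Without Foxd1-Cre replicate 2, 3 or 5 or wild-type replicate 4 or 6 that adjusted p lay between 0.0543 and 0.0776, above the threshold, and with each library rescaled to the same sum it was 0.112. Uncx (-0.32 ± 0.04), Sall1 (-0.43 ± 0.06), a zinc finger factor that kidney formation requires, and Meox1 (-0.95 ± 0.16) fell and Etv1 (0.46 ± 0.07) rose. The median was -0.10, with adjusted p = 0.0186 by camera and adjusted p = 0.467 with an estimated correlation. Committed nephron genes parted ways, with 4 of 22 up, 5 down and 13 not passing (4 and 7 adjusted over the list alone). Wnt4 (0.81 ± 0.08), the signal that starts epithelium formation, the cadherin Cdh6 (1.13 ± 0.10), Tmem100 (1.09 ± 0.10) and Osr2 (0.76 ± 0.22) rose. Fgf8 (-0.80 ± 0.08), needed for progenitors to survive as they form vesicles, Lhx1 (-1.05 ± 0.14), a vesicle transcription factor, the Notch ligand Dll1 (-0.59 ± 0.08), Pax8 (-0.66 ± 0.09) and Pou3f3 (-0.28 ± 0.08) fell. Osr2 and the falls after Fgf8 were named after their values were seen. The call of Osr2 ended without any 1 of Foxd1-Cre replicates 1, 3, 4 and 5 and wild-type replicates 2, 3, 4 and 6 (adjusted p from 0.0574 to 0.109). That of Pou3f3 (adjusted p = 0.0486) ended without any 1 of the 11 libraries except wild-type replicate 2 (adjusted p from 0.0505 to 0.114). That list's median of -0.20 did not pass camera (adjusted p = 0.109, and 0.0361 without wild-type replicate 2). Of 24 ureteric bud genes 2 rose, 3 fell and 19 did not pass (4 and 5 adjusted over the list alone), with a median of -0.00 (adjusted p = 0.696). Wnt11 (0.40 ± 0.08), made at the bud tips, and Krt19 (0.58 ± 0.16), named after its value was seen, rose, and Etv4 (-0.38 ± 0.05), Hoxb7 (-0.20 ± 0.03) and Sox8 (-0.26 ± 0.07) fell. The call of Sox8 ended without Foxd1-Cre replicate 2, 3 or 4 (adjusted p = 0.0559, 0.0580 and 0.0555), and that of Krt19 without any 1 of Foxd1-Cre replicates 2, 3 and 5 and wild-type replicates 1, 3, 4 and 5 (adjusted p from 0.0504 to 0.0906).

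Of 24 extracellular matrix genes 10 rose in Foxd1-Cre kidneys and 14 did not pass (12 adjusted over the list alone), among them the proteoglycan Bgn (1.10 ± 0.10) and Col6a2 (0.87 ± 0.11). The median was 0.35, with adjusted p = 3.4e-07 by camera and adjusted p = 0.456 with an estimated correlation. Wild-type replicate 5 had the lowest matrix score of set 1 (mean log2 value 4.19, against 4.57 to 4.81 in its other wild types) and lay apart on the first component of set 1 (28.9 against 10.5 to 16.1). Without it the matrix median was 0.26 (camera, adjusted p = 8.6e-07). Of 13 cartilage and bone genes 5 rose, with or without adjustment over the list alone, and 8 did not pass. They were the osteoblast regulators Sp7 (2.47 ± 0.08) and Runx2 (2.82 ± 0.10), Snorc (1.20 ± 0.10), Col11a1 (1.09 ± 0.13) and Sox6 (0.27 ± 0.08), the last named after its value was seen. The call of Sox6 ended without any 1 of Foxd1-Cre replicates 1 to 3 and wild-type replicates 1, 2, 3 and 5 (adjusted p from 0.0588 to 0.0836). The median was 0.26, with adjusted p = 5.2e-06 by camera and adjusted p = 0.146 with an estimated correlation. Of 18 hypoxia and glycolysis genes 12 rose and 6 did not pass (16 adjusted over the list alone), among them the prolyl hydroxylase P4ha1 (0.74 ± 0.11), Ldha (0.45 ± 0.07) and Aldoa (0.43 ± 0.06). Their median was 0.37, with adjusted p = 1.2e-08 by camera and adjusted p = 0.182 with an estimated correlation. Of 9 erythroid genes 3 fell and 6 did not pass (7 adjusted over the list alone), namely the erythropoietin receptor Epor (-0.48 ± 0.05), Slc4a1 (-0.55 ± 0.14) and Alas2 (-0.51 ± 0.13). Their median was -0.51, with adjusted p = 4.5e-04 by camera and adjusted p = 0.391 with an estimated correlation. The calls of Slc4a1 and Alas2 ended without Foxd1-Cre replicate 3 (adjusted p = 0.0561 and 0.0580) or 5 (0.0555 and 0.0682), and that of Alas2 also without Foxd1-Cre replicate 1 (0.0561) or 2 (0.0602) or wild-type replicate 4 (0.0505).

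By limma, 1182 of 13996 genes rose and 674 fell in Foxd1-Cre kidneys within library set 1. Against all 9 wild types 897 of 14014 rose and 337 fell, and 91.3% of those calls were made within the set in the same direction. With the erythroid score as a covariate 973 genes were called within the set. Of 28 lists tested 14 passed camera, of which the Wnt list alone held with an estimated correlation, and 14 passed fry, which asks whether a list's genes move on balance one way and compares them with no other genes. With all 9 wild types as controls 15 lists passed camera, the same 14 and the committed nephron list (adjusted p = 0.0107), and Wnt targets, cortical stroma, cartilage and bone and BMP signalling held with an estimated correlation. The call of imprinted growth genes ended there without Foxd1-Cre replicate 1 (adjusted p = 0.0532). Six2 did not pass there (-0.13 ± 0.11, adjusted p = 0.460), Foxd1 fell by 2.16 ± 0.12, and Ebf2 took the place of Mme among the largest falls (-1.61, and -1.38 within the set).

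The Six2-Cre comparison asked the same of beta-catenin active in nephron progenitors. Falls were called for 15 of 22 progenitor, 12 of 24 ureteric bud and 8 of 9 erythroid genes, and rises for 13 of 22 Wnt target, 18 of 20 endothelial, 11 of 14 mural and 11 of 15 neural genes. With an estimated correlation camera called 0 lists in this comparison (10 at an unadjusted p under 0.05, and 21 by fry). Six2 (ENSMUSG00000024134, chromosome 17, 85684277 to 85688274) was at 18.0 ± 0.266 FPKM (SD, n = 3) against 80.8 ± 8.95 FPKM (SD, n = 3), a change of -2.10 ± 0.08 (SE) on the log2 scale (adjusted p = 1.5e-04). Foxd1 was at 71.3 ± 4.02 FPKM (SD, n = 3) against 74.1 ± 6.73 FPKM (SD, n = 3) and did not pass (-0.05 ± 0.08, adjusted p = 0.710). The largest rises were those of Notum (4.19 ± 0.17), the transcription factor Msx1 (3.90 ± 0.12), Runx1 (3.30 ± 0.09), a regulator of blood formation, and Tmem132c (3.00 ± 0.19). Mir6942 (89.8 ± 33.3 FPKM, SD, n = 3) and Snord92 (80.1 ± 38.3 FPKM, SD, n = 3) were listed at 0 in the wild types of set 2. Snora33 was listed at 0 in all 3 Six2-Cre libraries and was at 94.8 ± 26.4 FPKM (SD, n = 3) in the wild types. These small RNAs lie within Zkscan3, Wdr43 and Rps12, so their reads may come from those genes. They are also far shorter than 1 kilobase, so 1 read is worth more FPKM than for a transcript of 1 kilobase. Their values may therefore rest on few reads, and a value of 0 may reflect depth. The largest other falls were those of Cited1 (-3.08 ± 0.12), a marker of uncommitted progenitors, Dcx (-2.71 ± 0.10), a microtubule-binding protein, Nckipsd (-2.49 ± 0.19), Rasef (-2.45 ± 0.10) and Capn6 (-2.34 ± 0.08).

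Of 22 nephron progenitor genes measured in Six2-Cre kidneys, 15 fell, 1 rose and 6 did not pass (17 and 2 adjusted over the list alone). Cited1, Six2, the Six2 partner Eya1 (-1.54 ± 0.06) and Uncx (-1.43 ± 0.08) led the falls, and Etv1 (0.75 ± 0.11), named after its value was seen, rose. The median was -0.84, with adjusted p = 7.0e-11 by camera and adjusted p = 0.0852 with an estimated correlation. Committed nephron genes went both ways, with 7 of 22 up, 5 down and 10 not passing (8 and 8 adjusted over the list alone). Wnt4 rose (0.72 ± 0.07), and among the falls were Osr2 (-2.08 ± 0.23), Npnt, which fell by 1.00 ± 0.06, Ccnd1 (-0.69 ± 0.05) and Pax8 (-0.64 ± 0.09), the last named after its value was seen. The median of -0.05 did not pass camera (adjusted p = 0.756). Of 24 ureteric bud genes 12 fell and 12 did not pass (17 adjusted over the list alone), among them the keratins Krt8 (-0.71 ± 0.06) and Krt18 (-0.81 ± 0.08) and the GDNF receptor Gfra1 (-0.59 ± 0.05). The median was -0.35, with adjusted p = 5.8e-08 by camera and adjusted p = 0.0852 with an estimated correlation.

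Of 22 Wnt target genes 13 rose, 2 fell and 7 did not pass in Six2-Cre kidneys (15 and 2 adjusted over the list alone). Dkk1 (2.54 ± 0.07), Apcdd1 (2.86 ± 0.08) and Nkd1 (1.88 ± 0.07) rose, and the cyclin Ccnd1 and the ubiquitin ligase Rnf43 (-0.59 ± 0.10), named after their values were seen, fell. The call of Rnf43 ended without Six2-Cre replicate 2 or 3 or wild-type replicate 7 or 8 (adjusted p from 0.0522 to 0.0565). The median was 1.05, with adjusted p = 7.7e-09 by camera and adjusted p = 0.0852 with an estimated correlation.

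Of 20 endothelial genes 18 rose in Six2-Cre kidneys and 2 did not pass, with the same counts adjusted over the list alone, among them the adhesion molecule Pecam1 (0.76 ± 0.05), the VEGF receptor Kdr (0.92 ± 0.07) and the tight junction gene Cldn5 (1.05 ± 0.08). Pecam1 was at 32.1 ± 1.07 FPKM (SD, n = 3) against 18.6 ± 0.797 FPKM (SD, n = 3). The median was 0.76, with adjusted p = 2.5e-14 by camera and adjusted p = 0.0852 with an estimated correlation. Endothelial scores (mean log2 value) averaged 4.14 in Six2-Cre kidneys, 3.45 in the wild types of set 2 and 3.89 in those of set 1, and against all 9 wild types 8 of the 20 rose, with a median of 0.33 (camera, adjusted p = 2.2e-04, and adjusted p = 0.496 with an estimated correlation). Of 14 genes of mural, mesangial and renin cells 11 rose, 2 fell and 1 did not pass (12 and 2 adjusted over the list alone). The PDGF receptor Pdgfrb (1.31 ± 0.05), the potassium channel subunit Abcc9 (1.56 ± 0.12) and Mcam (0.63 ± 0.08) rose, and Des (-0.86 ± 0.11) and Gata3 (-0.27 ± 0.07), named after their values were seen, fell. The call of Gata3, which is also a member of the ureteric bud list, ended without Six2-Cre replicate 1 or 3 or wild-type replicate 7, 8 or 9 (adjusted p from 0.0712 to 0.138). The median was 0.87, with adjusted p = 9.4e-07 by camera and adjusted p = 0.0852 with an estimated correlation. Erythroid genes moved the other way in the same libraries, with 8 of 9 down and 1 up, also when adjusted over the list alone. The embryonic globins Hbb-y (-0.93 ± 0.09) and Hba-x (-0.82 ± 0.09) fell, and Epor rose (0.76 ± 0.15), named after its value was seen. The call of Epor ended without Six2-Cre replicate 1 or 3 or wild-type replicate 7 or 9 (adjusted p from 0.0629 to 0.0831). Near-identical globin copies can share reads. The erythroid median was -0.87, with adjusted p = 2.3e-05 by camera and adjusted p = 0.271 with an estimated correlation.

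Of 15 genes of neural crest, neurons and Schwann cells 11 rose in Six2-Cre kidneys and 4 did not pass (12 adjusted over the list alone), among them Fabp7 (1.90 ± 0.19), found in glia, and Dbh (2.34 ± 0.25), of noradrenaline synthesis. The median was 1.29, with adjusted p = 9.4e-07 by camera and adjusted p = 0.114 with an estimated correlation. Of 18 medullary stroma genes 9 rose, 3 fell and 6 did not pass (11 and 4 adjusted over the list alone). Fhl2 (1.26 ± 0.06), Snai2 (0.92 ± 0.05) and Lef1 (1.30 ± 0.09) rose, and Rspo3 (-1.17 ± 0.10), a Wnt agonist, Alx1 (-0.50 ± 0.09) and Cdkn1c (-0.21 ± 0.04) fell, the last 2 named after their values were seen. The call of Cdkn1c ended without any 1 of the 3 Six2-Cre libraries or wild-type replicates 7 and 8 (adjusted p from 0.0504 to 0.0720), and that of Alx1 without Six2-Cre replicate 1 or 3 or wild-type replicate 7, 8 or 9 (from 0.0505 to 0.0735). The median was 0.48, with adjusted p = 0.00398 by camera and adjusted p = 0.102 with an estimated correlation. Of 21 cortical stroma genes 5 rose, 2 fell and 14 did not pass (6 and 3 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.173). Among the rises were Ecm1 (1.46 ± 0.11), Meis1 (0.32 ± 0.04), Slitrk6 (0.83 ± 0.17) and Clca3a1 (0.59 ± 0.12), and Ntn1 (-1.52 ± 0.14) and Smoc2 (-1.42 ± 0.16) fell, of which Slitrk6 and Clca3a1 were named after their values were seen. Their calls ended without Six2-Cre replicate 3 or wild-type replicate 7, 8 or 9, and that of Clca3a1 also without Six2-Cre replicate 1 (adjusted p from 0.0550 to 0.0908). Of 24 matrix genes 13 rose, 1 fell and 10 did not pass (16 and 2 adjusted over the list alone), among them Bgn (0.96 ± 0.09) and, as the fall, the basement membrane laminin Lama1 (-0.54 ± 0.10), named after its value was seen. The call of Lama1 ended without Six2-Cre replicate 2 (adjusted p = 0.0558) or wild-type replicate 7 (0.0590) or 8 (0.0654). The median was 0.36, with adjusted p = 8.8e-07 by camera and adjusted p = 0.271 with an estimated correlation.

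By limma, 1097 of 13828 genes rose and 808 fell in Six2-Cre kidneys within library set 2. Against all 9 wild types 2747 of 14014 rose and 3697 fell, and 22.8% of those calls were made within the set in the same direction. Rescaling to the same sum turned that balance to 3645 up and 2454 down, as did asking for a change of at least 2-fold (498 and 341). The total of 6444 was 3895, 3733 or 3613 without Six2-Cre replicate 1, 2 or 3. With the erythroid score as a covariate limma called 0 genes within set 2, with 1630 at an unadjusted p under 0.05. The covariate separates the groups of set 2 (erythroid score 4.08 ± 0.15 against 4.60 ± 0.11, SD, n = 3 and 3), and Six2 changed by -2.10 ± 0.08 without it and by -2.23 with it (adjusted p = 0.109). Without Six2-Cre replicate 1, 2 or 3 the count within the set was 1088, 1020 or 907, and without wild-type replicate 7 or 8 it was 1099 or 1024. Of 28 lists 14 passed camera within the set, 0 of them with an estimated correlation (10 at an unadjusted p under 0.05), and 21 passed fry. With all 9 wild types as controls 10 lists passed camera, of which Wnt targets and mural cells held with an estimated correlation. Erythroid (adjusted p = 0.132, and 0.0425 without wild-type replicate 1), macrophage (0.493), imprinted growth (0.0744) and hypoxia and glycolysis genes (0.550) did not pass there. Six2 fell by 2.39 ± 0.13 and Foxd1 did not pass (-0.36 ± 0.15, adjusted p = 0.0584). The largest changes against all 9 wild types were mostly of small RNAs. Rmrp, the RNA of a ribonuclease, changed by 8.30 on the log2 scale against all wild types and by 0.23 within the set (adjusted p = 0.353), and Mir6236 by -7.48 and -2.79 (adjusted p = 0.0980). Mir432 (5.47 and 2.90), Scarna6 (4.07 and 0.59), Ap5z1 (-3.37 and -2.59) and Defb25 (-2.69 and -2.70) did not pass within the set either.

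The 2 mutant effects were then set against each other, to ask where stromal and progenitor activation of beta-catenin differ. Each effect was taken against the wild types of its own set, and the Six2-Cre effect was subtracted from the Foxd1-Cre effect. The effect on Six2 was higher in Foxd1-Cre kidneys by 1.84 ± 0.11 (SE) on the log2 scale and that on Foxd1 was lower (-2.27 ± 0.13). The effect on Ctnnb1 did not differ past the threshold (-0.10 ± 0.07, adjusted p = 0.389). Penk (3.78 ± 0.47), an opioid peptide precursor, Efhd1 (3.13 ± 0.27), the homeobox gene Alx1 (3.10 ± 0.13) and Amhr2 (2.90 ± 0.36), the anti-Müllerian hormone receptor, had the higher effect in Foxd1-Cre kidneys. Runx1 (-3.09 ± 0.11), Rnase12 (-3.04 ± 0.49), Dkk1 (-2.99 ± 0.12) and the metallothionein Mt3 (-2.87 ± 0.28) had the lower. Penk was at 55.6 ± 12.2 FPKM (SD, n = 5) in Foxd1-Cre kidneys and at 2.97 ± 1.02 FPKM (SD, n = 3) in Six2-Cre kidneys, against 7.17 ± 3.21 FPKM (SD, n = 6) and 6.75 ± 3.38 FPKM (SD, n = 3) in their wild types. With a pseudocount of 0.1 the differences of Amhr2 and Rnase12 did not pass (adjusted p = 0.074 and 0.056). Mapkapk3 (3.15 ± 0.85, adjusted p = 0.0457) lost its call without any 1 of 10 libraries (Foxd1-Cre replicates 1 and 3, Six2-Cre replicates 1 to 3 and wild-type replicates 1, 2, 4, 7 and 9, adjusted p from 0.0504 to 0.138). Snora33, Mir6942 and Snord92, which were listed at 0 in a group of set 2 and may rest on few reads, differed too.

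**Figure D3:**
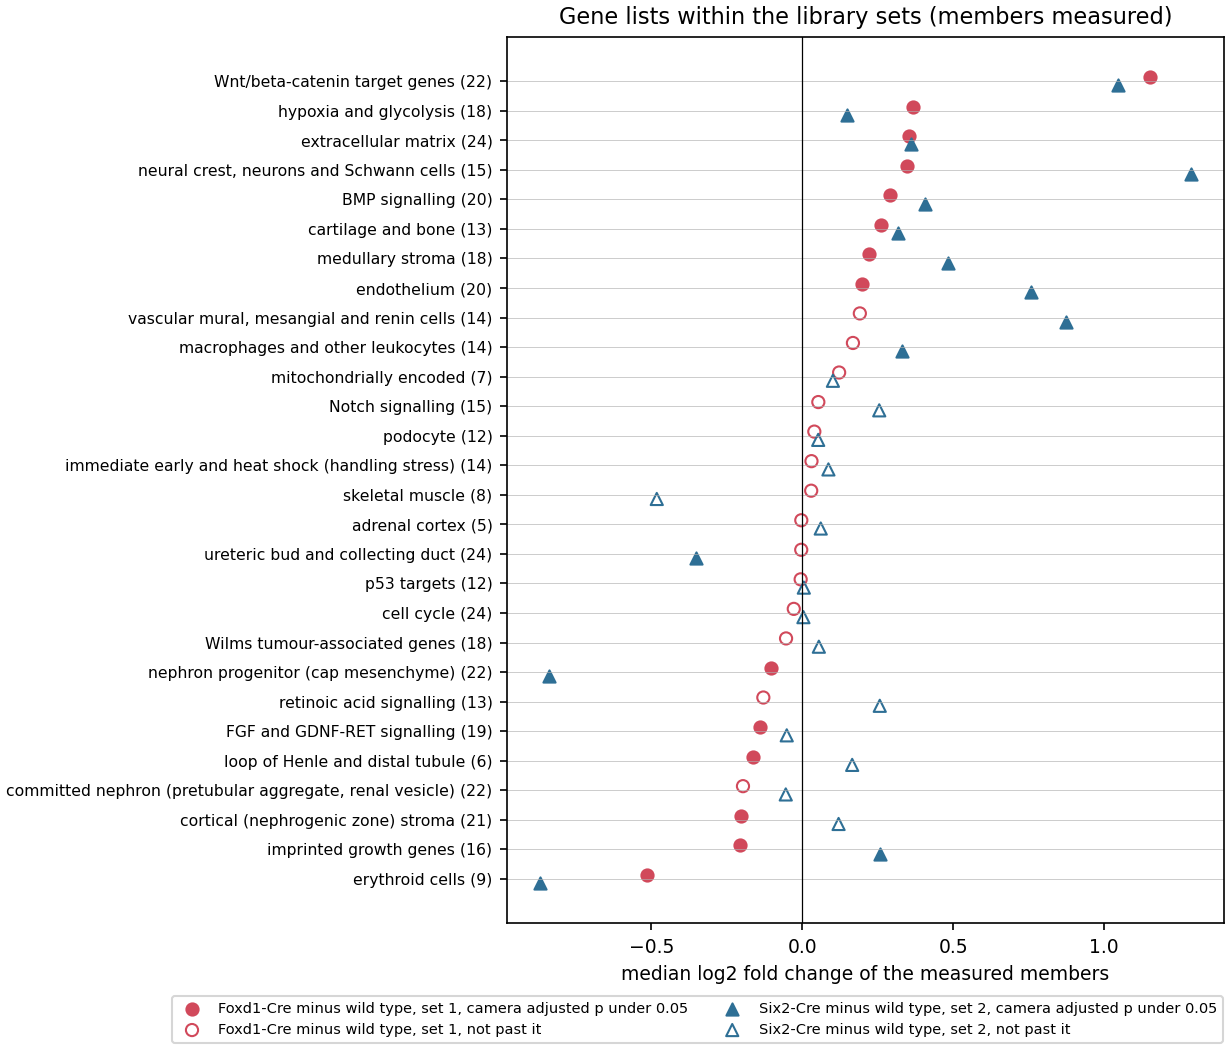
Median log2 change of each gene list within its library set for Foxd1-Cre and Six2-Cre kidneys (x axis), with 1 line per list (y axis) and filled points where camera's adjusted p is under 0.05. Wnt targets lie at 1.15 and 1.05, nephron progenitor genes at -0.10 and -0.84, and endothelial genes at 0.20 and 0.76.

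Nephron progenitor genes had the higher effect in Foxd1-Cre kidneys for 14 of 22 members, with 8 not passing (14 and 1 adjusted over the list alone). Cited1 (2.51 ± 0.16), Rspo1 (1.89 ± 0.13) and Eya1 (1.39 ± 0.13) were among them. The median difference was 0.72, with adjusted p = 8.7e-09 by camera and adjusted p = 0.131 with an estimated correlation. Ureteric bud genes had the higher effect for 12 of 24, with 12 not passing (17 adjusted over the list alone), among them Krt8 (0.74 ± 0.10) and Cdh16 (1.00 ± 0.14). Their median was 0.46, with adjusted p = 2.8e-05 by camera and adjusted p = 0.475 with an estimated correlation. Wnt targets were split, with 11 of 22 higher, 4 lower and 7 not passing (13 and 4 adjusted over the list alone). Apcdd1 (2.03 ± 0.13), Nkd1 (1.49 ± 0.11) and Kremen1 (1.19 ± 0.09) had the higher effect in Foxd1-Cre kidneys. Dkk1, Msx1 (-2.12 ± 0.14), Sp5 (-1.19 ± 0.14) and Msx2 (-0.99 ± 0.25) had the lower, of which Msx1, Sp5 and Msx2 were named after their values were seen. The call of Msx2 ended without Foxd1-Cre replicate 1, any 1 of the Six2-Cre libraries or wild-type replicate 4 or 8 (adjusted p from 0.0536 to 0.144). The median was 0.65, with adjusted p = 0.00195 by camera and adjusted p = 0.476 with an estimated correlation.

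Endothelial genes had the lower effect in Foxd1-Cre kidneys for 15 of 20 members, with 5 not passing (17 adjusted over the list alone), among them Cldn5 (-0.87 ± 0.13) and Cd34 (-0.52 ± 0.10). The median was -0.53, with adjusted p = 5.0e-09 by camera and adjusted p = 0.349 with an estimated correlation. Mural cell genes were lower for 6 of 14, higher for 2 and did not pass for 6 (7 and 2 adjusted over the list alone), with Abcc9 (-1.71 ± 0.16), Kcnj8 (-1.81 ± 0.22) and Pdgfrb (-1.13 ± 0.11) lower and Gata3 (0.47 ± 0.09) and Des (0.64 ± 0.19), named after their values were seen, higher. The call of Des ended without Foxd1-Cre replicate 1 or 2, Six2-Cre replicate 1 or 3 or wild-type replicate 1, 5, 6, 7 or 8 (adjusted p from 0.0536 to 0.0845). Their median was -0.58, with adjusted p = 0.00235 by camera and adjusted p = 0.138 with an estimated correlation. Cortical stroma genes were lower for 8 of 21 and did not pass for 13 (9 lower and 1 higher adjusted over the list alone), led by Foxd1, Aldh1a2 (-1.51 ± 0.09), Fibin (-1.71 ± 0.10) and Ecm1 (-1.39 ± 0.16). Their median was -0.10 and their mean -0.37, with adjusted p = 6.4e-04 by camera and adjusted p = 0.138 with an estimated correlation. The median was -0.040 without Foxd1-Cre replicate 1, -0.17 without Six2-Cre replicate 3, -0.15, -0.061 and -0.17 without wild-type replicates 2, 3 and 7, and camera's call held. Medullary stroma genes went both ways, 6 higher and 5 lower of 18 (also adjusted over the list alone), with a median of -0.05, a mean of 0.32 and an upward camera result that did not pass (adjusted p = 0.801). Imprinted growth genes were lower for 8 of 16 and did not pass for 8 (10 adjusted over the list alone), among them H19 (-0.76 ± 0.06), Peg10 (-1.31 ± 0.14) and the growth factor Igf2 (-0.73 ± 0.10). Their median was -0.47, with adjusted p = 3.2e-06 by camera and adjusted p = 0.131 with an estimated correlation. Of 9 erythroid genes 1, Epor (-1.25 ± 0.16), differed between the effects past the threshold, and the list's median of 0.32 did not pass camera (adjusted p = 0.867).

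By limma, 795 of 13810 genes had the higher and 724 the lower effect in Foxd1-Cre kidneys. The lower were the more with rescaling to the same sum (689 and 694) and without wild-type replicate 5 (761 and 766) or 7 (586 and 605). Comparing the mutants directly, across the library sets, gave 5108 higher and 3397 lower of 14014, of which 13.2% were called in the same direction between the effects and 2130 had the opposite sign. The excess of higher genes in the direct comparison shrank with median-of-ratios scaling (4222 and 4110) and turned with rescaling to the same sum (3874 and 4162) or a change of at least 2-fold (718 and 804). The genes with the largest direct differences were small RNAs and histones. Rmrp (-12.93), Rpph1 (-12.14) and the histone genes Hist1h4f (-10.60), Hist1h4m (-10.19), Hist1h4a (-10.00) and Hist1h4h (-9.77) were lower in Foxd1-Cre libraries on the log2 scale. Between the effects Rmrp (-0.82), Rpph1 (-0.36), Hist1h4f (-0.32), Hist1h4m (-0.14), Hist1h4a (0.026) and Hist1h4h (0.15) did not pass. Mir675 (12.70), Mir5114 (9.46), Mir6236 (9.17), Mir8114 (9.00), Mir762 (8.47) and Mir6340 (8.08) were higher directly, and Mir6236 (2.15) and Mir762 (2.15) did not pass between the effects. Copies of histone H4 are near-identical and can share reads, and Mir675 lies within H19. Of 28 lists 9 passed camera between the effects, 0 of them with an estimated correlation (4 at an unadjusted p under 0.05), and 9 passed fry. Comparing the mutants directly, 3 lists passed camera (cortical stroma, neural and imprinted growth genes), 0 of them with an estimated correlation (3 at an unadjusted p under 0.05), and 11 passed fry. Wnt targets (adjusted p = 0.508), nephron progenitor (0.0646), ureteric bud (0.0646), mural (0.0577), endothelial (0.225) and Notch genes (0.159) did not pass camera. The neural call ended without Foxd1-Cre replicate 2 or 3, Six2-Cre replicate 3 or wild-type replicate 5, 7 or 8 (adjusted p from 0.0501 to 0.0615). Mural genes passed without Foxd1-Cre replicate 4 or 5, Six2-Cre replicate 1 or 2 or wild-type replicate 1 (from 0.0275 to 0.0467), and nephron progenitor (0.0447) and ureteric bud genes (0.0360) without Foxd1-Cre replicate 4.

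Across 13810 genes the Foxd1-Cre and Six2-Cre effects, each within its own set and so with separate controls, had a Pearson correlation of 0.262 and a covariance of 0.0347. Genes are not independent replicates, so no p is given. The mutants rose together at 374 genes and fell together at 151, where independent lists would share 93.4 and 39.3. A rise in Foxd1-Cre and a fall in Six2-Cre kidneys met at 31 genes and the reverse at 61, where independent lists would share 68.8 and 53.3. Notum, Apcdd1, Axin2, Nkd1, Lef1, Tubb3 and Bgn rose in both, and Ntn1, Cited1 and Uncx fell in both. With all 9 wild types shared by both mutants the correlation was -0.469 and the covariance -0.156. Unchanged groups simulated against the same shared controls gave a correlation of 0.282 and a covariance of 0.0125 without the difference between the library sets, and -0.784 and -0.207 with it. Splitting the controls, with wild-type replicates 1 to 5 for Foxd1-Cre and 6 to 9 for Six2-Cre, gave a correlation of 0.233 and a covariance of 0.0360. That split placed replicate 6, of library set 1, among the Six2-Cre controls. The opposite split gave -0.791 and -0.657. It set Six2-Cre against wild types of set 1 alone and Foxd1-Cre mostly against those of set 2. Its values therefore hold the difference between the sets and do not measure the agreement of the mutant effects.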

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

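The tests of explanations for the call counts, for Foxd1 and for the endothelial genes, and the splits of the libraries within the library sets, were chosen only after the data had been seen, while the splits against all wild types and of the mutants compared directly were planned.

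A library far from the others of its group was found for 11 of 328 gene values tested in groups of 4 to 10, where chance flags about 1 in 20 groups. Foxd1-Cre replicate 4 was far from the other 4 libraries for Alas2 (6.49 FPKM against 3.68 to 4.30), Alx1 (29.9 against 22.4 to 24.5), Myocd (3.15 against 2.08 to 2.20), Tmem100 (13.6 against 10.2 to 10.9) and Mir432 (7.72 FPKM, with the others listed at 0). Foxd1-Cre replicate 5 stood apart for Snord92 (7.33 FPKM, with the others listed at 0) and Foxd1-Cre replicate 1 for C1qc (5.85 against 7.19 to 7.54). Among the 9 wild types, replicate 2 stood apart for Bgn (31.4 FPKM against 18.9 to 25.1) and Clca3a1 (4.00 against 1.95 to 2.57), replicate 9 for Ebf2 (8.33 against 2.55 to 5.45) and replicate 7 for Gdf10 (3.05 against 0.462 to 1.39). The 9 wild types were tested as 1 group over both library sets, and replicates 7 and 9 belong to set 2, so the difference between the sets was not kept out of Ebf2 and Gdf10.

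The effects of the mutants, each against the wild types of its own library set, differed by a test of the difference itself for the genes below, in log2 terms and as Foxd1-Cre minus Six2-Cre effect. Among nephron progenitor and ureteric bud genes those that differed were Six2 (1.84), Cited1 (2.51), Rspo1 (1.89), Eya1 (1.39), Krt8 (0.74) and Cdh16 (1.00). Among stromal genes they were Foxd1 (-2.27), Aldh1a2 (-1.51), Fibin (-1.71), Ecm1 (-1.39) and Alx1 (3.10). Wnt pathway genes that differed were Apcdd1 (2.03), Nkd1 (1.49), Kremen1 (1.19), Dkk1 (-2.99), Msx1 (-2.12), Sp5 (-1.19) and Msx2 (-0.99). Vascular and blood genes were Abcc9 (-1.71), Kcnj8 (-1.81), Pdgfrb (-1.13), Des (0.64), Gata3 (0.47), Cldn5 (-0.87), Cd34 (-0.52), Runx1 (-3.09) and Epor (-1.25). Of these, Gata3 is also a member of the ureteric bud list. Neural and Notch genes were Stmn2 (-1.80), Fabp7 (-1.87), Tubb3 (1.57), Hes1 (-0.32), Hey1 (-0.34), Hey2 (-0.90) and Jag1 (-0.68). Imprinted genes were H19 (-0.76), Igf2 (-0.73) and Peg10 (-1.31). The others were Amhr2 (2.90), Efhd1 (3.13), Mapkapk3 (3.15), Penk (3.78), Mt3 (-2.87), Rnase12 (-3.04), Mir6942 (-6.74), Snora33 (6.24) and Snord92 (-5.60). The calls of Mapkapk3, Msx2 and Des rest on single libraries and those of Amhr2 and Rnase12 on the pseudocount, as the results state. Those of Mir6942, Snora33 and Snord92 may rest on few reads. By camera at the preset correlation, lists that differed were Wnt targets (median 0.65), nephron progenitor (0.72), ureteric bud (0.46), cortical stroma (-0.10), mural cells (-0.58), endothelium (-0.53), neural cells (-0.84), imprinted growth genes (-0.47) and Notch signalling (-0.29), of which 0 passed with an estimated correlation (4 at an unadjusted p under 0.05). Camera's call ended without Six2-Cre replicate 3 for neural (adjusted p = 0.0603) and Notch genes (0.0561), and for Notch genes without wild-type replicate 5 (0.0508) or 8 (0.102). The cortical stroma median ran from -0.17 without Six2-Cre replicate 3 or wild-type replicate 7 to -0.040 without Foxd1-Cre replicate 1, and was -0.15 and -0.061 without wild-type replicates 2 and 3.

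Six2-Cre kidneys had 6444 calls against all 9 wild types and 1905 against the wild types of set 2. Without Six2-Cre replicate 1, 2 or 3 these were 3895, 3733 or 3613 and 1088, 1020 or 907, and the count within the set was 1099 or 1024 without wild-type replicate 7 or 8. Lower depth of set 2 alone is argued against, since 7.86% of 5190 genes with a mean of at least 20 FPKM differed at least 2-fold between the wild types of the sets. The library set itself stays as an explanation, with 9172 genes called between wild types. Whether RNA without a poly(A) tail was kept in set 2 but not in set 1 stays open. The 4 small nuclear and 8 small Cajal body RNA genes were higher in the wild types of set 2 by a median of 4.74 (SD 3.15, 12 genes; 4 and 5 called). Histone cluster genes, most of whose transcripts lack the tail, were higher too (median 7.76, 58 of 60 higher and 1 lower), as were 3 ribozyme genes (median 11.8). Unlike these, 108 small nucleolar RNA genes, which lack it as well, had a median of 0.18, with 21 higher and 20 lower. The 320 microRNA genes had a median of -1.52, with 28 higher and 100 lower. Why these classes of small RNA moved differently was not tested. A biological difference between the wild types of the sets (litter, strain or stage) was not tested.

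Foxd1 was lower in Foxd1-Cre kidneys by more than loss of 1 gene copy would give, a change of -1 on the log2 scale, since the 95% interval of its change ran from -2.54 to -2.10. Fewer stromal cells are argued against as the whole cause by the other cortical stroma genes, whose median change was -0.10 (SD 0.74, 20 genes). Repression of Foxd1 or an altered identity of stromal cells under active beta-catenin stays open as a biological explanation and was not tested.

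In Six2-Cre kidneys 18 of 20 endothelial genes rose. Fewer nephron-lineage cells with every other cell type raised alike are argued against by the ureteric bud genes, whose median lay 1.11 below that of endothelium (spread 0.41). This cannot tell whether ureteric bud cells were fewer as well. A larger share of endothelial cells through loss of other cell types therefore stays open. A single deviating library is argued against as well, since the lowest Six2-Cre endothelial score (mean log2 value) lay 0.59 above the highest wild-type score of set 2. Adrenal or sympathetic tissue carried along in dissection stays open. The log2 value (pseudocount 1) of the summed FPKM of 5 steroidogenic genes differed by -0.094 (spread 0.21), but the sums, 0.396 to 0.853 FPKM, lie near the floor of set 2 (1 read on 1 kilobase is 0.171 to 0.189 FPKM) and exclude nothing. In the same libraries 11 of 15 neural genes rose, among them Dbh (2.34), of noradrenaline synthesis. A change in the endothelium itself stays open too, and the fall of 8 of 9 erythroid genes is confounded with the same groups.

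For the split tests, libraries were regrouped at random into groups of the real sizes. For Foxd1-Cre within set 1, 1 of 100 splits, the real one, reached 1856 calls, the highest other split gave 710, and chance was excluded. For Six2-Cre within set 2 the real split gave 1905 and the highest other 11, and 10 splits are too few for a share under 0.05. For the difference of the effects 4 of 100 splits gave at least the real 1519, and the highest other gave 2566. All 4 kept the Six2-Cre and wild-type libraries of set 2 apart, as 13 of the 100 did, and the 87 others gave at most 8. That share therefore follows how seldom set 2 is drawn parted, and chance was not excluded. Against all 9 wild types, 5 of 100 splits reached the 1234 calls for Foxd1-Cre, and chance was not excluded. The highest other gave 6146, several times the real count, and a split that placed wild-type replicates 7 to 9 with Foxd1-Cre replicates 1 and 2 gave 6059, which points to the library sets as a structure of the samples. For Six2-Cre 1 of 100 splits reached 6444 and the highest other gave 4584, while wild-type replicates 7 to 9 in the place of the Six2-Cre libraries gave 2104. All Six2-Cre libraries belong to set 2, so these splits cannot tell an effect of genotype from the library sets, and no verdict on chance is drawn. For the mutants compared directly 1 of 56 splits reached 8505, the highest other gave 3 and chance was excluded, but the real split is also the split of the library sets.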

How the results depend on the processing

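Each library set by itself, protein-coding genes only and the joint fits were chosen only after the data had been seen, and the other alternatives were planned. Where no cause is given below, the cause was not tested.

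Against all 9 wild types, limma called 1234 genes for Foxd1-Cre, 6444 for Six2-Cre and 8505 between the mutants. The Foxd1-Cre count was 801 with a minimum of 5 FPKM, which leaves fewer genes to test, 2801 with library weights and 476 with the erythroid covariate. The Six2-Cre count was 10244 with library weights, 10068 with the replicate block and 3840 with the compared groups only, which uses fewer libraries. Replicate numbers 6 to 9 occur only in wild types, so with the block those libraries add nothing to the comparisons. They include every wild type of set 2. The block's Six2-Cre count and correlation therefore rest on wild types of set 1 and hold the difference between the sets. A change of at least 2-fold was met by 182, 839 and 1522 of the calls, fewer by construction. Each library set by itself gave 1856, 1905 and 1519. The correlation of the effects was -0.469 and turned positive with library weights (0.113), the erythroid covariate (0.471), the replicate block (0.183) and each set by itself (0.262). By itself each set also reversed Ctnnb1 for Six2-Cre (0.24) and between the mutants (-0.10), and Hist1h4a (0.026) and Hist1h4h (0.15) between the mutants, since it removes the difference between the sets.

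With all 9 wild types camera called 15 lists for Foxd1-Cre, 10 for Six2-Cre and 3 between the mutants. With an estimated correlation it called 4, 2 and 0, the last with 3 at an unadjusted p under 0.05 and 11 by fry. Fry called 16 for Six2-Cre and 11 between the mutants, the replicate block left 1 between the mutants, and each set by itself gave 9. Cartilage and bone genes between the mutants were called upward by fry, with a median of 0.41, where camera's direction was down, and the cause was not tested.

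Within the sets, the erythroid covariate left 973 of 1856 calls for Foxd1-Cre, 0 of 1905 for Six2-Cre (limma, 1630 at an unadjusted p under 0.05) and 67 of 1519 for the difference, and moved the correlation from 0.262 to 0.0795. This covariate separates the groups of set 2, so it cannot be told apart from genotype there. The fall of Six2 in Six2-Cre kidneys was no smaller with it, as the results state, and why the calls were lost was not tested. A change of at least 2-fold was met by 190, 273 and 280. Protein-coding genes only gave a correlation of 0.369, and the joint fit with equal weights gave 3638 calls for Six2-Cre. With an estimated correlation camera called 1, 0 and 0 lists, the zeros with 10 and 4 lists at an unadjusted p under 0.05 and 21 and 9 by fry.

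Leaving out 1 library at a time gave 938 to 1401, 3613 to 8017 and 6935 to 8952 genes against all wild types, and 1423 to 1922, 907 to 1467 and 1036 to 1527 within the sets. The Six2-Cre count against all wild types was 3895, 3733 and 3613 without Six2-Cre replicates 1, 2 and 3. Within set 2 it was 1088, 1020 and 907 without them and 1099 and 1024 without wild-type replicates 7 and 8. Fewer libraries were used there. Lists called ran from 15 to 17, 10 to 11 and 2 to 9 against all wild types (9 without Foxd1-Cre replicate 4 and 6 without Six2-Cre replicate 1) and from 12 to 15, 14 to 15 and 7 to 9 within the sets. The correlation ran from -0.492 to -0.376 and from 0.234 to 0.284.

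Rescaling to the same sum moved the share of rises among the calls against all wild types from 42.6% to 59.8% for Six2-Cre and from 60.1% to 48.2% between the mutants, and the median of all genes from -0.06 to 0.05 and from 0.12 to 0.00. Quantile normalization moved it from 72.7% to 62.0% for Foxd1-Cre. Within set 1 the share of 63.7% became 53.1% with quantile normalization and 75.1% with rescaling to the same sum.

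Replicate numbers are shared between the groups, and same-numbered libraries deviated together weakly at most. Within set 1 the same-numbered pairs of Foxd1-Cre and wild-type libraries were all positive (0.0224 to 0.0993). Differently numbered pairs of these groups there ran from -0.1435 to 0.109. The other same-numbered pairs joined libraries of different sets. A weak pairing within set 1 is therefore not excluded. Of 11 pairs 0 had a correlation over 0.1, with a lowest of -0.0227, a median of 0.0224 and a highest of 0.0993. With the replicate block over both sets 1458, 10068 and 9887 genes were called for Foxd1-Cre, for Six2-Cre and between the mutants, and 1425 for Foxd1-Cre within set 1. Wild-type replicates 6 to 9, whose numbers no other group shares, add nothing to these comparisons. Six2-Cre was thus set against wild types of set 1 there. Within set 2 no paired analysis was possible because its wild types and mutants share no numbers.

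Outside leaving libraries out, values of named genes within the sets stayed on their side of the threshold in 2679 cases, lost it in 216 and gained it in 1. Against all wild types these were 564, 19 and 9, with 4 reversed. Without 1 library the losses were 182 of the values within the sets and 16 of those against all wild types. List results kept their side in 310 cases within the sets, lost it in 42 and gained it in 12, and against all wild types in 439, 33 and 31, with 1 reversed. Depth limits small values most in set 2, where 1 read on a transcript of 1 kilobase is 0.171 to 0.189 FPKM against 0.0266 to 0.0347 FPKM in set 1.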

Other observations

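The values within each library set were chosen as the leading ones only after the data had been seen, and the tests of gene lists were planned.

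In Foxd1-Cre kidneys 11 of 20 BMP signalling genes rose, 1 fell and 8 did not pass (12 and 2 adjusted over the list alone), among them the BMP antagonists Grem1 (1.61 ± 0.12) and Fst (0.86 ± 0.11) and the ligand Bmp4 (0.85 ± 0.10), with a fall in Chrdl1 (-0.37 ± 0.08), named after its value was seen. The median was 0.29, with adjusted p = 5.3e-05 by camera and adjusted p = 0.273 with an estimated correlation. In Six2-Cre kidneys 11 of them rose, 2 fell and 7 did not pass (12 and 2 adjusted over the list alone), among them the BMP target genes Id1 (0.61 ± 0.05), Id2 (0.57 ± 0.03) and Id3 (0.65 ± 0.06) and Bmp4 (1.74 ± 0.11). The progenitor survival factor Bmp7 (-0.84 ± 0.11) and Chrdl1 (-0.79 ± 0.13), named after their values were seen, fell. The median was 0.40, with adjusted p = 1.4e-05 by camera and adjusted p = 0.0852 with an estimated correlation. Between the effects the list did not pass (adjusted p = 0.804). Imprinted growth genes fell in Foxd1-Cre kidneys for 6 of 16, rose for 1 and did not pass for 9 (7 and 2 adjusted over the list alone), with falls in Mest (-0.56 ± 0.04) and the maternally expressed H19 (-0.29 ± 0.04), and a rise in Sgce (0.34 ± 0.07), named after its value was seen. Their median was -0.21, with adjusted p = 0.0299 by camera and adjusted p = 0.467 with an estimated correlation. Camera's call ended without Foxd1-Cre replicate 1 (median -0.12, adjusted p = 0.0521) or wild-type replicate 4 (-0.22, 0.0622), and without wild-type replicate 5 it held with a median of -0.12. In Six2-Cre kidneys 7 of them rose, 2 fell and 7 did not pass (also adjusted over the list alone), with rises in Peg10 (1.39 ± 0.07), H19 (0.47 ± 0.05) and Igf2 (0.52 ± 0.05). The falls were in Cdkn1c (-0.21 ± 0.04), whose fragile call stands in the results, and Grb10 (-0.15 ± 0.04), named after its value was seen. The call of Grb10 ended without any 1 of the 6 libraries (adjusted p from 0.0811 to 0.132). The median was 0.26, with adjusted p = 0.0036 by camera and adjusted p = 0.114 with an estimated correlation.

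Neural genes in Foxd1-Cre kidneys rose for 5 of 15, fell for 1 and did not pass for 9 (8 and 1 adjusted over the list alone). Tubb3 (2.99 ± 0.11), a neuronal tubulin, Prph (0.78 ± 0.18), Hand2 (0.86 ± 0.20), and, named after their values were seen, Th (0.96 ± 0.27) and Dbh (1.23 ± 0.35) rose, and Stmn2 (-0.97 ± 0.13) fell. The calls of Th and Dbh ended without any 1 of Foxd1-Cre replicates 4 and 5 and wild-type replicates 1, 2, 3, 4 and 6 (adjusted p from 0.0546 to 0.0920). The median was 0.35, with adjusted p = 0.00598 by camera and adjusted p = 0.456 with an estimated correlation. Endothelial genes in the same kidneys rose for 4 of 20 and did not pass for 16 (7 adjusted over the list alone), with a median of 0.20, adjusted p = 0.00204 by camera and adjusted p = 0.589 with an estimated correlation. Flt1 (0.40 ± 0.08), a VEGF receptor, kept its call without any 1 library, and the calls of Pecam1 (0.29 ± 0.08), Emcn (0.21 ± 0.06) and Sox18 (0.29 ± 0.09) ended without any 1 of Foxd1-Cre replicates 2 to 5 and wild-type replicates 1, 3, 5 and 6, and that of Emcn also without wild-type replicate 4 (adjusted p from 0.0516 to 0.116). FGF and GDNF-RET signalling genes fell for 6 of 19, rose for 2 and did not pass for 11 (10 and 2 adjusted over the list alone). Fgf8, Etv4 (-0.38 ± 0.05) and Fgfr1 (-0.21 ± 0.03) fell and Fgf20 (0.27 ± 0.04), named after its value was seen, and Fgfr2 (0.60 ± 0.05) rose. The median was -0.14, with adjusted p = 0.0256 by camera and adjusted p = 0.467 with an estimated correlation. Camera's call ended without Foxd1-Cre replicate 2 (adjusted p = 0.0529), and with rescaling to the same sum the call of Fgfr1 ended (adjusted p = 0.0544). Loop of Henle and distal tubule genes fell for 2 of 6 (also adjusted over the list alone), Mecom (-0.83 ± 0.07) and Pou3f3, whose call is described in the results, with a median of -0.16, adjusted p = 0.0493 by camera and adjusted p = 0.467 with an estimated correlation. Camera's call ended without any 1 of Foxd1-Cre replicates 2 to 5 and wild-type replicates 1, 5 and 6 (adjusted p from 0.0558 to 0.103, and 0.0874 without wild-type replicate 5, which lay apart).

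In Six2-Cre kidneys cartilage and bone genes rose for 5 of 13 and did not pass for 8 (6 adjusted over the list alone). They were Sox5 (1.00 ± 0.09), Col9a1 (1.30 ± 0.14), Hapln1 (0.50 ± 0.08), Runx2 (1.52 ± 0.33) and Col11a1 (0.55 ± 0.14), the last named after its value was seen. The call of Hapln1 ended without Six2-Cre replicate 3 (adjusted p = 0.0527). That of Runx2 ended without Six2-Cre replicate 1, 2 or 3 or wild-type replicate 7 (adjusted p = 0.0915, 0.0591, 0.0907 and 0.0694), and that of Col11a1 without any 1 of the Six2-Cre libraries or wild-type replicate 7 or 9 (adjusted p from 0.107 to 0.137). The list's median was 0.32, with adjusted p = 7.3e-04 by camera and adjusted p = 0.102 with an estimated correlation. Macrophage genes rose for 3 of 14 and did not pass for 11 (4 adjusted over the list alone), namely the complement gene C1qb (0.54 ± 0.08), Mrc1 (0.59 ± 0.10) and C1qc (0.57 ± 0.13). The median was 0.33, with adjusted p = 0.0123 by camera and adjusted p = 0.375 with an estimated correlation, and without wild-type replicate 8 camera's call ended (median 0.17, adjusted p = 0.0926). The call of Mrc1 ended without Six2-Cre replicate 1 (adjusted p = 0.0507) or 3 (0.0550), and that of C1qc without Six2-Cre replicate 1 or 2 or wild-type replicate 7, 8 or 9 (adjusted p from 0.0714 to 0.101). Hypoxia and glycolysis genes rose for 3 of 18 and did not pass for 15 (3 adjusted over the list alone), namely Bnip3 (0.53 ± 0.08), Egln3 (0.64 ± 0.12) and P4ha1 (0.41 ± 0.08). The median was 0.15, with adjusted p = 0.00516 by camera and adjusted p = 0.302 with an estimated correlation. The call of Egln3 ended without any 1 of the Six2-Cre libraries or wild-type replicate 8 (adjusted p from 0.0600 to 0.0740), and that of P4ha1 without Six2-Cre replicate 1 or 3 or wild-type replicate 7 or 8 (adjusted p from 0.0677 to 0.0786).

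Between the effects, neural genes were lower in Foxd1-Cre kidneys for 4 of 15 and higher for 1, Tubb3 (1.57 ± 0.17), with 10 not passing (8 and 2 adjusted over the list alone), among them Stmn2 (-1.80 ± 0.22) and Fabp7 (-1.87 ± 0.23). The median was -0.84, with adjusted p = 0.0145 by camera and adjusted p = 0.481 with an estimated correlation, and camera's call ended without Six2-Cre replicate 3 (adjusted p = 0.0603). Notch signalling genes were lower for 4 of 15 and did not pass for 11 (5 lower and 2 higher adjusted over the list alone), namely Hes1 (-0.32 ± 0.06), Hey2 (-0.90 ± 0.18), Jag1 (-0.68 ± 0.15) and Hey1 (-0.34 ± 0.09). The median was -0.29, with adjusted p = 0.0303 by camera and adjusted p = 0.481 with an estimated correlation. Camera's call ended without Six2-Cre replicate 3 (adjusted p = 0.0561), wild-type replicate 5 (0.0508) or wild-type replicate 8 (0.102).

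Other lists did not pass camera in either mutant within its set. These were cell cycle (adjusted p = 0.109 in Foxd1-Cre and 0.401 in Six2-Cre kidneys), Wilms tumour-associated genes (0.109 and 0.696), Notch signalling (0.692 and 0.103), retinoic acid signalling (0.453 and 0.158), p53 targets (0.520 and 0.532), podocyte (0.453 and 0.462), adrenal cortex (0.290 and 0.382), skeletal muscle (0.927 and 0.0871), mitochondrially encoded genes (0.220 and 0.462) and handling stress genes (0.927 and 0.151). Their medians lay between -0.48 for skeletal muscle in Six2-Cre kidneys and 0.26 for retinoic acid signalling in the same kidneys. Median and mean differed in sign for Notch signalling in Foxd1-Cre kidneys (0.05 and -0.04, camera downward), for p53 targets there (-0.01 and 0.08, camera upward) and for Wilms tumour-associated genes in Six2-Cre kidneys (0.05 and -0.09, camera downward). Mural cell genes in Foxd1-Cre kidneys (median 0.19, adjusted p = 0.109), macrophage genes there (0.17, 0.118) and loop of Henle genes (0.17, 0.563) and FGF and GDNF-RET genes (-0.05, 0.563) in Six2-Cre kidneys did not pass either. Between the effects, cartilage and bone, cell cycle, extracellular matrix, hypoxia and glycolysis and the other lists not named as passing had adjusted p from 0.106 to 0.867. Leaving out 1 library brought some of these lists past camera's threshold. In Foxd1-Cre kidneys these were cell cycle without wild-type replicate 5 (adjusted p = 0.0121) or 4 (0.0413) or Foxd1-Cre replicate 1 (0.0396) or 4 (0.0428), Wilms tumour-associated genes without wild-type replicate 5 (0.0237), macrophage genes without wild-type replicate 2 (0.0170) or 4 (0.0431), mitochondrially encoded genes without wild-type replicate 3 (0.0445) and mural cell genes without Foxd1-Cre replicate 1 (0.0427). In Six2-Cre kidneys they were Notch signalling without wild-type replicate 7 (0.0474) and skeletal muscle without wild-type replicate 8 (0.00435, and 0.00850 between the effects).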
